A study of Mus musculus with 6 samples.

How the data were processed

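RNA of 3 control and 3 labelled Cux2 knock-out samples of mouse cerebral cortex was examined, 1 array per sample. Per the labels, RNA was amplified, labelled with Cy3 and hybridised to 1-colour Agilent arrays. Groups come from the sample titles, which give each sample its own number. The labels do not state in so many words that each sample is a separate animal, so p-values measure the spread between these samples. The titles of the controls read wild type and their genotype label reads Cux2+/-, and they are called controls. No replicate number is shared between groups, so no pairing was made.

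Per the file headers, spots were quantified with Agilent Feature Extraction 9.1.3.1, and the processed signal is an intensity that was background-subtracted and spatially detrended within each array, with surrogate values for dim spots. The mean spot signal and the local background median are intensity values with no further correction, per the file headers. The flags for spots well above background, outliers and saturation were set by the same software. The authors also deposited a table of log2 values. All of its columns have the same distribution (median 6.75 in each) and rank as the processed signal of the same array, so they are on a log2 scale and quantile normalized by that comparison. Neither a centring nor a direction beyond this is stated. The genome build behind the array annotation is not given in the sources used here.

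Of 45018 spots per array, 1639 control spots were left out, as were 120 spot values with an outlier flag over the 6 arrays, and 0 spots were saturated. Spots of one probe were averaged, which left 41174 probes. The main values are log2 of the processed signal minus each array's 75th percentile. A probe was tested where it was well above background on all 3 arrays of at least 1 group, which gave 25505 probes. This filter uses the group labels, so a probe bright in only 1 group can enter because the groups differ. Probes were named by accession through a gene table of the assembly GRCm38.p6 (22951 probes), by symbol (6659) or by synonym (3109), and 8455 kept the name of the array file. The brightest probe over all arrays stood for each of 17122 genes, and 5975 genes had several tested probes. No coordinates are printed, and the table served for names and gene order.

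Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 (package data.table, version 1.17.8), with Benjamini-Hochberg adjustment over all tested probes at 0.05. Intervals are 95% intervals of that fit. A probe well above background on no array of a group has only a bound there, and where only some arrays of a group measured a called probe of a named gene their number is given. For the bound, the brighter group's mean was set against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Gene lists were tested with camera of limma at a preset correlation of 0.01, two-sided, with adjustment over 28 lists, beside camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way and, in its mixed form, in either direction. Position on chromosome 5 was tested with a two-sided Fisher's exact test over 14101 genes with a place, within 20 Mb of Cux2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

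The lists, the tests, the rule for named genes and most of the alternative settings were fixed before the data were examined. The lists hold markers of upper-layer and deep-layer neurons, interneurons, oligodendrocytes, astrocytes, microglia, vessel cells, red blood cells, meninges, choroid plexus, striatum, hippocampus, thalamus and olfactory bulb. Further lists hold spine and postsynaptic, presynaptic, glutamate receptor, GABA receptor, axon guidance, progenitor and cell cycle, activity-regulated, clock and glucocorticoid, heat shock, interferon and MHC, Xlr, chromosome 5 neighbour, sex-linked and reference genes. Named genes are Cux2, then up to 12 genes with the largest rise and 12 with the largest fall among those past the threshold whose groups do not overlap, passing over clone names and filling with the genes of lowest p. From each list up to 4 members of lowest p are eligible to be named, with every measured Xlr gene.

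The 6 arrays lie on 2 slides, 1 control with 2 knock-outs on slide 1 and 2 controls with 1 knock-out on slide 2, and slide was fitted as a block and its values given within each slide. Alternatives changed the scaling between arrays, the background correction (normexp with offset 50), the filter on dim probes, the variance model, array weights, the summary of probes, the slide block, the authors' deposited log2 values and the arrays left out. The procedure was tested on simulated data for the comparison of knock-out with control, with 50 changed probes per fold among 25443. It recovered 24% of probes changed 1.5-fold, 76% at 2-fold, 98% at 4-fold and 100% at 8-fold, with 9 false calls. The camera step on 17098 simulated genes called the microglia list at a shift of -0.4 and 0 other lists. Its noise was drawn independently for each gene, so it cannot show how camera at the preset correlation behaves where genes are correlated.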

Results

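Gene expression was measured in 6 samples of cerebral cortex from male mice, 3 of them labelled Cux2 knock-out (samples 53, 48 and 54) and 3 of them controls (samples 15, 62 and 16). The controls are titled wild type while their genotype label reads Cux2+/-, and this conflict is not settled by the labels, so they are called controls here. Each sample was hybridised to its own 1-colour Agilent array of 45018 spots, with no technical repeats. The share of probes well above background was 62.7%, 67.1% and 72.7% on control arrays 15, 62 and 16, and 63.5%, 58.5% and 68.1% on knock-out arrays 53, 48 and 54. Correlations of log2 signal across probes, which are not independent replicates, lay between 0.991 and 0.994 within groups and between 0.988 and 0.991 between groups. The number of arrays limits the precision, and the age of the animals is not given in the sources used here.

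Cux2, a homeodomain transcription factor of upper-layer cortical neurons, was measured first because it is the targeted gene. Its brighter probe stood at 0.09 ± 0.16 in controls and -0.03 ± 0.02 in the labelled knock-outs (log2 signal relative to the array's 75th percentile, SD, n = 3 each). The difference was -0.12 with a 95% interval of -0.36 to 0.12 (limma, adjusted p = 0.838). A dimmer probe, which the array file names by a cDNA clone and the gene table assigns to Cux2, differed by 0.08 (limma, adjusted p = 0.947). Where these probes lie relative to the altered part of the allele is not given in the sources used here, so they check nothing about the labels. The brighter probe's difference turned to +0.05 without scaling between arrays, a setting that moved the median of all genes by 0.17.

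The question of the design was which transcripts differ between cortex labelled Cux2 knock-out and control cortex. Of the genes that rose in the labelled knock-outs, Tescl was highest by the fitted value of 5.15 on the log2 scale (SE 0.21), and because it was not well above background on any control array it is given as at least 12.3-fold higher. Rbm45, an RNA-binding protein, rose by 3.11 (SE 0.12), and Exoc3l2, a relative of exocyst subunits, rose by 2.04 (SE 0.23). Of those that fell, Ccl21c, a chemokine that acts through Ccr7, fell by 4.23 (SE 0.35), Zfp605, a zinc-finger protein, fell by 3.14 (SE 0.25) and Tlr1, a Toll-like receptor, fell by 2.76 (SE 0.21). Adat2, the catalytic subunit of a tRNA adenosine deaminase, fell by 2.18 (SE 0.22), all with n = 3 arrays per group in limma.

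In all, 33 probes passed an adjusted p of 0.05 (13 higher, 20 lower), of 25505 tested. By the brightest probe of each gene these were 22 genes, 10 higher and 12 lower, and for all 22 the 3 knock-out arrays lay on one side of the 3 controls. Such separation was seen in 2333 of 17122 genes, or 13.6%, where chance gives 10%. A call with 3 arrays per group all but requires such separation, so it adds no support for the 22 genes. Named genes that also rose were Fam47e (+1.99, limma adjusted p = 0.00845), Stbd1, a glycogen-binding protein (+1.43, adjusted p = 0.0167), Ifnz, a type I interferon (+1.35, adjusted p = 0.0145), Bmp2k, a protein kinase (+0.96, adjusted p = 0.0323), and Uty. Uty, a Y-linked relative of a histone demethylase, rose 2.84-fold (adjusted p = 0.0191) and was well above background on 2 of 3 control arrays. Named genes that also fell were Sox2ot, a long non-coding RNA overlapping Sox2 (-2.13, adjusted p = 0.0191), Rpp25, a subunit of ribonuclease P (-1.47, adjusted p = 0.0287), Hyi, a hydroxypyruvate isomerase (-1.22, adjusted p = 0.0232), and Actb, cytoplasmic beta-actin (-1.17, adjusted p = 0.0167). For the genes named first, adjusted p was 0.00125 for Tescl, 0.00125 for Rbm45, 0.0461 for Exoc3l2, 0.0167 for Ccl21c, 0.0149 for Zfp605, 0.0145 for Tlr1 and 0.0346 for Adat2. Tlr1 was well above background on 1 of 3 knock-out arrays. Ccl21c has near-identical paralogs, so which copy the probe measured is uncertain. The other 6 called genes carry clone or accession names, 2 of them higher and 4 lower. Of the 22 genes, 4 were well above background on no array of 1 group. The filter on dim probes used the group labels, so these entered through the group in which they were bright. Filters blind to the labels called fewer genes. They called 16 with probes well above background on all 6 arrays, 3 with at least 1 array and 2 without a filter. In the last 2 settings 0 genes were lower.

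**Figure D1:**
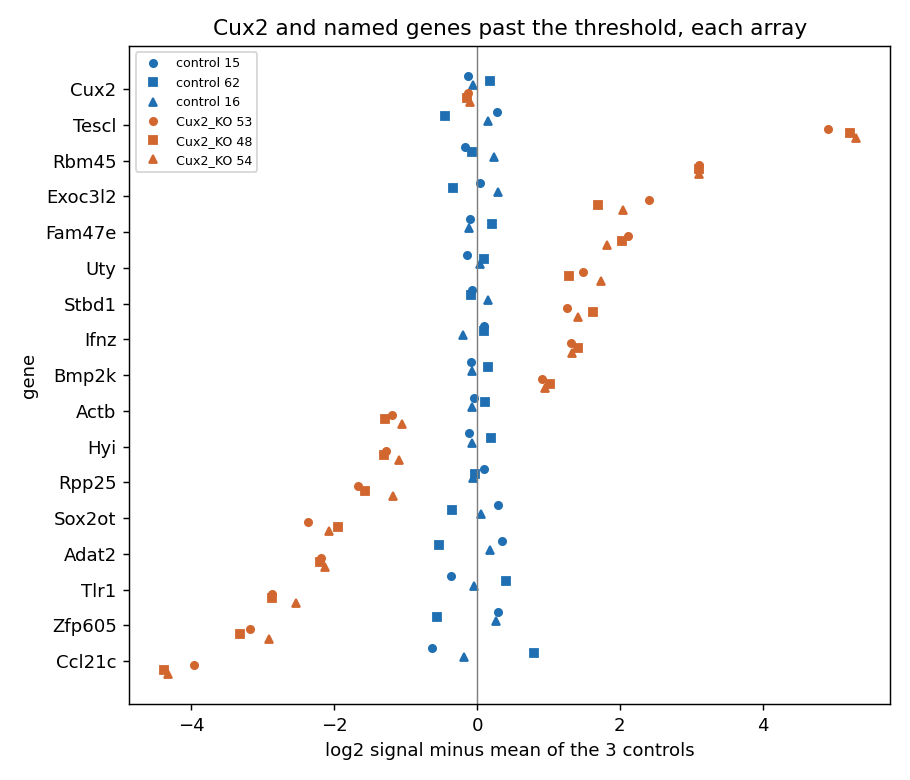
Log2 signal of Cux2 and of each named gene past the threshold on each of the 6 arrays, minus the mean of the 3 controls (blue, controls; orange, labelled knock-outs; marker shapes tell arrays apart). The 3 knock-out arrays lie on one side of the 3 controls for every gene plotted except Cux2, as the rule for named genes past the threshold requires.

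The named-gene rule filled the remaining places with genes that did not pass. Higher values were +1.30 for Tmem138, +0.67 for Nkapl, +0.67 for Arsk and +0.66 for Parvg, with limma adjusted p from 0.0572 to 0.0791. Lower values were -1.66 for Timmdc1, -1.26 for Tmem132d, -0.95 for Olfml2a and -0.77 for Cetn4, with adjusted p from 0.0622 to 0.0793. Probes of one gene often differed. For Bmp2k 3 other probes stood between -0.22 and -0.08, and for Sox2ot the other probes stood at -1.69 and +2.01, none of them past the threshold. A second Stbd1 probe rose by 1.43, whereas a second Arsk probe fell by 1.74 against the +0.67 of its brighter probe. Second probes of Slx1b, a structure-specific endonuclease subunit, Pkd2, a polycystin channel, Hsd17b11 and Aldh2 differed by -5.54, -2.69, -1.66 and -1.61, each past the threshold while the brightest probe of the same gene was not. The second probes of Arsk and Slx1b were well above background on 1 and 2 of 3 knock-out arrays, and Olfml2a on 1 of 3. Over 14 genes with a called probe and another tested probe, another probe moved the same way at an unadjusted p under 0.05 in 4.

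With slide as a block 9 of the 22 called genes stayed past the threshold (limma adjusted p over the 22 from 0.00306 to 0.101). All 22 had the same sign within both slides, which the separation of their groups makes certain, so it is no further check. Of the named genes Ifnz, Rpp25, Stbd1, Actb, Uty, Adat2, Hyi, Bmp2k and Exoc3l2 no longer passed. Their differences stayed of similar size, as at 2.12 for Exoc3l2, -2.27 for Adat2 and -1.17 for Actb. Leaving out control 15, control 16 or knock-out 54 lowered the 33 probes to 7, 2 and 12, and leaving out knock-out 53 raised them to 60.

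Microglial markers were lower together in the labelled knock-outs: all 16 measured members were below control, by a mean of -0.44 on the log2 scale. Over all genes tested 0 passed in limma (13 at an unadjusted p under 0.05), and 12 fell adjusted over the list alone. Among them were Ly86, a partner of a Toll-like receptor homologue, at -1.02 (SE 0.21), Tmem119 at -0.37 (SE 0.09), and the complement components C1qc at -0.63 (SE 0.15) and C1qb at -0.77 (SE 0.21). Camera of limma with a preset correlation of 0.01 called the list lower (adjusted p = 3.42e-11), but the call was lost at adjusted p = 0.354 with an estimated correlation. The mean was -0.41 within slide 1 and -0.44 within slide 2, and slide as a block gave camera adjusted p = 2.34e-09 at the preset and 0.429 at an estimated correlation. Markers of striatum, tissue next to the cortex, were lower on average too but did not follow the microglial ones array by array: control 16, the highest array for microglia at 0.40, was the lowest control for striatum. The striatal list stood at 0.50, 0.50 and -0.24 on control arrays 15, 62 and 16 and at -0.37, -0.12 and -0.27 on knock-out arrays 53, 48 and 54, as log2 deviation from each gene's mean.

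All 13 measured striatal markers were lower, by a mean of -0.51 (camera, adjusted p = 2.05e-06), with Drd1, a dopamine receptor, at -0.77 and Sh3rf2 at -0.75, and 0 members passed over all genes or adjusted over the list alone (2 at an unadjusted p under 0.05). The striatal call was lost at adjusted p = 0.755 with an estimated correlation. Clock and glucocorticoid-responsive genes were lower in 16 of 18 (mean -0.25, camera adjusted p = 8.61e-05), 7 of them at an unadjusted p under 0.05 in limma. Of these 0 passed over all genes and 2 fell adjusted over the list alone, the clock repressors Per2 at -0.58 and Per1 at -0.56, and the list had adjusted p = 0.354 with an estimated correlation. The clock list's mean was -0.16 without control 15, which stood at 0.30, while controls 62 and 16 stood at 0.01 and 0.06. Astrocyte markers were lower in 15 of 16 (mean -0.15, camera adjusted p = 0.00591), with the intermediate filament Gfap at -0.58 and the calcium-binding S100b at -0.30, 0 past the threshold over all genes or adjusted over the list alone (3 at an unadjusted p under 0.05), and adjusted p = 0.390 with an estimated correlation. The 4 measured members of the sex-linked list, Y-linked genes with no X-inactivation gene among them, were all higher (mean 0.51, camera adjusted p = 0.00123). Of these only Uty passed, both over all genes and adjusted over the list alone, while Eif2s3y stood at +0.25, Kdm5d at +0.24 and Ddx3y at +0.04 (-0.011 without knock-out 54), and the list had adjusted p = 0.354 with an estimated correlation. These were the 5 of 28 lists past the threshold by camera with the preset correlation, 1 higher and 4 lower, and 0 of 28 passed with an estimated correlation (lowest adjusted p = 0.354) or with fry, also of limma (lowest adjusted p = 0.0739). At an unadjusted p under 0.05 these tests gave 3 and 5 lists. Fry's mixed test, of change in either direction and without comparison to other genes, passed 7 of 28 lists: upper-layer markers (adjusted p = 3.35e-04), reference genes (adjusted p = 3.35e-04), clock genes (adjusted p = 0.00429), sex-linked genes (adjusted p = 0.0111), microglia (adjusted p = 0.0145), chromosome 5 neighbours (adjusted p = 0.0176) and progenitor genes (adjusted p = 0.0388).

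**Figure D2:**
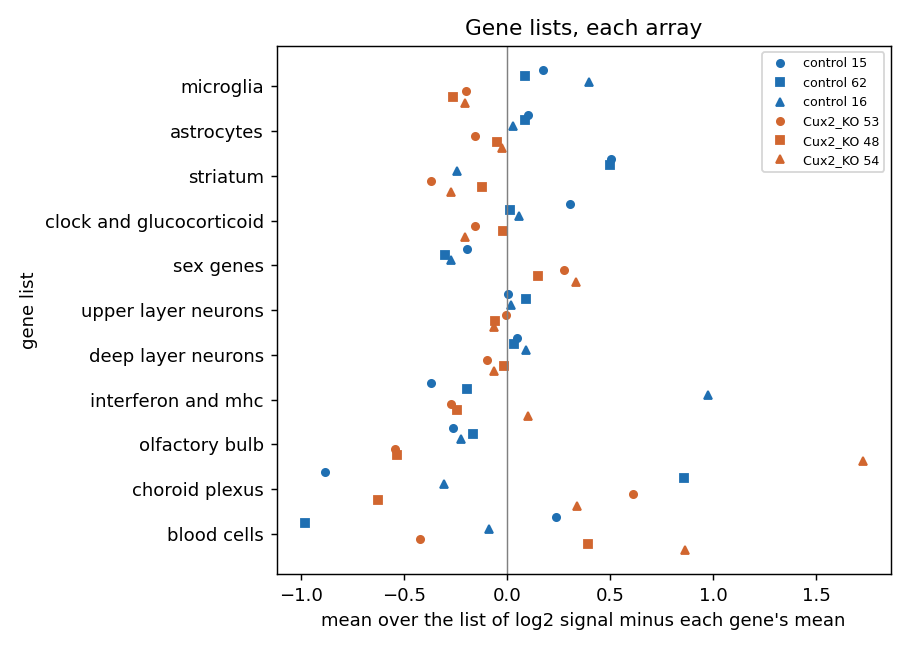
Mean log2 deviation of 11 gene lists on each of the 6 arrays (blue, controls; orange, labelled knock-outs). The microglia list lies between 0.09 and 0.40 on the control arrays and between -0.26 and -0.20 on the knock-out arrays, while the olfactory bulb list stands apart at 1.73 on knock-out array 54.

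Markers of upper-layer neurons, in which Cux2 is known to act, and of deep-layer neurons did not pass camera's threshold as groups in the main setting. Over 22 alternatives with the preset correlation deep-layer markers passed in 5 (adjusted p from 0.00288 to 0.262) and upper-layer markers in 1, without a filter on dim probes (adjusted p from 0.0352 to 0.679). With an estimated correlation adjusted p was 0.390 for deep-layer and 0.841 for upper-layer markers in the main setting. Of 21 upper-layer markers 6 were higher and 15 lower (mean -0.08, camera adjusted p = 0.424), and 0 passed over all genes, while adjusted over the list alone Limch1, an actin-associated protein whose gene lies on chromosome 5 as Cux2 does, fell by 1.44, Dtx4 fell by 0.39 and the potassium channel Kcnh5 rose by 0.44. An unadjusted p under 0.05 in limma was reached by 3 higher and 4 lower upper-layer markers of the 21, against 1416 of all 17122 genes. Such a share was not particular to this list. It was reached by 5 of 20 deep-layer markers, 2 higher and 4 lower of 22 progenitor genes, and 7 lower of 18 clock genes. Among interneuron and presynaptic genes 0 reached it. Of 20 deep-layer markers 3 were higher and 17 lower (mean -0.12, adjusted p = 0.0845), with the subcerebral-projection factor Fezf2 at -0.52. Interneuron markers gave a mean of -0.01 with 8 of 19 higher (adjusted p = 0.745), and Tac1, shared with the striatal list, stood at -0.57. Spine and postsynaptic genes gave 0.02 with 19 of 34 higher (adjusted p = 0.656) and presynaptic genes 0.01 with 13 of 25 higher (adjusted p = 0.656). Glutamate receptor subunits gave 0.01 with 12 of 21 higher (adjusted p = 0.789), GABA receptor subunits -0.01 with 7 of 14 higher (adjusted p = 0.789) and axon guidance genes 0.02 with 18 of 27 higher (adjusted p = 0.420). In these 7 lists, deep-layer markers to axon guidance genes, 0 members passed in limma over all genes or adjusted over the list alone, while an unadjusted p under 0.05 was reached by 5 deep-layer markers, 2 spine genes, 1 GABA receptor subunit and 1 axon guidance gene. The GABA receptor mean and median were below 0 while camera's direction was up.

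Other cell types and responses gave 0 members past the threshold over all genes or adjusted over the list alone in 11 lists with limma, while an unadjusted p under 0.05 was reached by 6 progenitor genes, 3 activity-regulated genes, 2 vessel markers and 2 thalamic markers. The mean was 0.00 for progenitor and cell cycle genes (adjusted p = 0.683), 0.07 for activity-regulated genes (adjusted p = 0.420) and 0.01 for heat shock genes (adjusted p = 0.754). It was -0.03 for oligodendrocyte markers (adjusted p = 0.745), 0.08 for vessel cells (adjusted p = 0.420), 0.03 for meninges (adjusted p = 0.573) and 0.56 for red blood cell transcripts (adjusted p = 0.0747). For neighbouring tissue it was 0.22 for choroid plexus (adjusted p = 0.420), 0.01 for hippocampus (adjusted p = 0.963), -0.09 for thalamus (adjusted p = 0.403) and 0.43 for olfactory bulb (adjusted p = 0.477). Interferon-response and MHC class I genes were lower in 16 of 19 (mean -0.27, adjusted p = 0.0747), with 0 members past either adjustment or an unadjusted p of 0.05, and the mean was 0.30 within slide 1 and -0.66 within slide 2. Single arrays decided this mean, which was 0.14 without control 16 and -0.53 without control 15. The choroid plexus mean went from -0.17 without control 15 to 0.70 without control 62, that of olfactory bulb from -0.32 without knock-out 54 to 0.81 without knock-out 53, and that of red blood cell transcripts was 0.20 without control 62. In 14 of 28 lists the mean took both signs as single arrays were left out. With slide as a block 3 further lists passed camera's threshold with the preset correlation: activity-regulated genes (mean 0.21, camera adjusted p = 8.02e-04), choroid plexus (mean 0.54, camera adjusted p = 0.00419) and thalamus (mean -0.16, camera adjusted p = 0.0211). With an estimated correlation these blocked values were 0.429, 0.724 and 0.552. Over 22 alternatives with the preset correlation the interferon and MHC list passed in 12 (adjusted p from 1.60e-05 to 0.296) and red blood cell transcripts in 6 (adjusted p from 0.00111 to 0.471). With an estimated correlation adjusted p was 0.864 and 0.841 for these lists in the main setting. Of 14 measured reference genes 1 fell over all genes and adjusted over the list alone, Actb, whose second probe stood at -0.78, and the list's mean was -0.04 (adjusted p = 0.700). For activity-regulated genes and hippocampus the median was below 0 while the mean and camera's direction were above.

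The Xlr genes of the X chromosome are known from published work of this laboratory on Cux2 mutants, so the list is not independent evidence. Xlr3c, named Xlr3b on the array, stood at +1.69 (SE 0.56, limma adjusted p = 0.521) and Xlr4b at +1.66 (SE 0.56, adjusted p = 0.525), both higher on all 3 knock-out arrays than on any control. Xlr stood at -0.27 (adjusted p = 0.702) and at +0.09 with normexp background correction and the 75th percentile. Over all genes 0 of the 3 measured members passed, and 2 rose adjusted over the list alone (list mean 1.03, camera adjusted p = 0.403). The list mean was 0.64 without control 62. Probes of this family cannot separate near-identical copies with certainty.

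Genes close to Cux2 on chromosome 5 were examined because DNA next to a targeted locus can be carried along from embryonic stem cells. The Cux2 allele and its origin are not given in the sources used here. Gene order came from the assembly GRCm38.p6. Of 18 called genes with a place, 6 lay on chromosome 5 (Tlr1, Fam47e, Stbd1, Bmp2k, Zfp605 and Actb), an odds ratio of 7.42 (95% interval 2.28 to 21.4, two-sided Fisher's exact p = 6.16e-04). The whole chromosome was not part of the planned test, which took 20 Mb around Cux2. Fisher's test counts genes as independent, while neighbours may move together, so its intervals and p-values here may be too narrow. Fam47e and Stbd1 among the 6 are next to one another in gene order. With slide as a block Stbd1, Actb and Bmp2k no longer passed (limma adjusted p = 0.0669, 0.0669 and 0.100). Within 20 Mb of Cux2 lay 1 of the 18, Zfp605, an odds ratio of 1.98 (95% interval 0.0472 to 12.7, exact p = 0.411), and within 40 Mb lay 5 (exact p = 5.54e-04). These counts take each gene's brightest probe. Counted by any probe past the threshold, a choice made after seeing the data, 4 of 28 genes lay within 20 Mb, namely Zfp605, Aldh2, Hsd17b11 and Pkd2 (odds ratio 5.64, 95% interval 1.42 to 16.5, exact p = 0.00816), and 1 of them, Aldh2, within 10 Mb. Of the 200 genes of lowest p, 20 lay within 20 Mb, an odds ratio of 3.87 (95% interval 2.28 to 6.24, exact p = 1.44e-06). For the same 200 the odds ratio was 2.47 (95% interval 0.968 to 5.28, exact p = 0.0290) within 10 Mb, 4.98 (95% interval 3.29 to 7.36) within 40 Mb and 3.57 (95% interval 2.42 to 5.15) on the whole chromosome. Among the 38 on the whole chromosome were Limch1 of the upper-layer list, Tmem119 of the microglia list and Tmem132d. By separate distances, singled out after the values were seen, they were 7 of 208 tested genes up to 10 Mb, 13 of 200 from 10 to 20 Mb, 13 of 155 from 20 to 40 Mb and 5 of 332 farther on chromosome 5, against 162 of 13206 elsewhere. Fam47e, Stbd1 and Sowahb lie next to one another among the tested genes, and Sowahb stood at +0.79 (adjusted p = 0.179), as Tlr6 beside Tlr1, well above background on 2 of 3 knock-out arrays, stood at -1.05 (adjusted p = 0.253). These neighbours were singled out after their values were seen. Of 34 measured neighbours of Cux2 listed in advance 15 were higher and 19 lower (mean -0.09, camera adjusted p = 0.403), 0 passed over all genes, and adjusted over the list alone the myosin light chain Myl2, well above background on 2 of 3 knock-out arrays, fell by 0.91 and the purinergic receptor P2rx7 fell by 0.61. Without knock-out 54, 0 of the called genes lay within 20 Mb, and Myl2 turned to +0.09 with normexp and the 75th percentile.

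**Figure D3:**
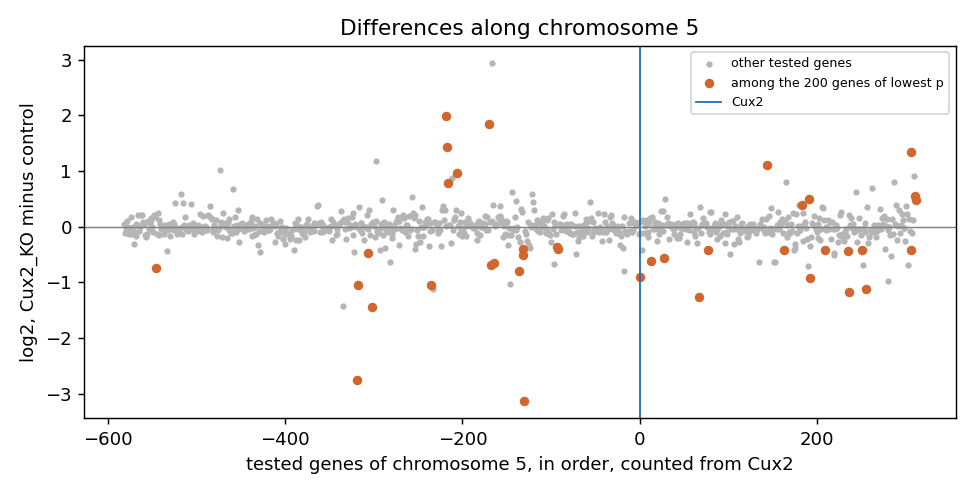
Log2 difference, labelled knock-out minus control, of each tested gene of chromosome 5 against its order counted from Cux2 (blue line). Orange points are the 38 of the 200 genes of lowest p that lie on this chromosome, and they stand on both sides of Cux2, with rises and falls.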

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

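The tests on normexp without bright-background spots, on the 200 genes of lowest p without the microglia list and on genes with any called probe near Cux2 were chosen only after seeing the data. The planned normexp fit with the 75th percentile called 0 probes. In it 6, 9 and 6 spots with local background up to 25638, 10500 and 42806 on control 16, knock-out 48 and knock-out 54 raised the fitted noise SD to 429, 159 and 513, against 0.708 to 1.09 on the other arrays. Without those spots 31 probes passed. With quantile normalization in place of the 75th percentile, normexp called 25 genes with those spots kept and 23 without them, so the 0 depends on the scaling too. In that limma fit with 0 calls 149 probes had an unadjusted p under 0.05, and each called gene's adjusted p was 0.988, the highest of its alternatives. Median scaling called 11 genes higher and 24 lower against 10 and 12 in the main setting. The microglia list stayed past camera's threshold in 22 of 22 settings with the preset correlation, at adjusted p from 8.30e-22 to 1.09e-07, but not with an estimated correlation (0.354) or with fry (0.0957). This was not particular to microglia. The striatum, clock and astrocyte lists also passed in 22 of 22 settings with the preset correlation, and the sex-linked list in 20. Among the named genes, Rbm45 was called in 21 of 22 settings and Tescl in 20, down to 10 for Bmp2k and Exoc3l2. Signal over background let 25505 of 41174 probes be tested, and each other filter on dim probes changed the number of tests as well as the count. Unless a cause is given here, the cause was not tested.

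With the median of each array as scale, counts were 24 genes lower and list adjusted p was 0.0219 for blood cells. Without scaling between arrays, counts were 16 genes higher and list adjusted p was 1.60e-05 for interferon and mhc. Under it, differences turned to 0.055 for Cux2, 0.040 for Syt1, 0.031 for Grm5, 0.066 for Hsp90ab1, 0.010 for Acsbg1, 0.014 for Epha5 and 0.013 for Dtx1. With normexp and the 75th percentile, counts were 0 probes past the threshold, 0 genes higher and 0 genes lower and the chromosome 5 odds ratio was 3.87 and list adjusted p was 0.00668 for deep layer neurons, 0.00340 for xlr family, 0.00403 for blood cells and 0.129 for sex genes. Under it, differences turned to 0.40 for Olfml2a, 0.087 for Xlr, 0.47 for Neurog2, 0.41 for Tdo2, 0.22 for Cabp7, 0.27 for Epha3, 0.095 for Myl2 and 0.066 for Hvcn1. With normexp and quantile normalization, list adjusted p was 0.0149 for interferon and mhc. With normexp fitted without spots of bright local background and the 75th percentile, list adjusted p was 0.0334 for deep layer neurons and 0.0128 for interferon and mhc. With the same fit and quantile normalization, list adjusted p was 0.0190 for interferon and mhc. Without a filter on dim probes, counts were 2 probes past the threshold, 2 genes higher, 0 genes lower and 10 lists past the threshold by camera and the chromosome 5 odds ratio was 3.39 and list adjusted p was 0.0352 for upper layer neurons, 0.00288 for deep layer neurons, 0.0352 for thalamus, 0.0125 for interferon and mhc and 0.0258 for chr5 neighbours. With probes well above background on all 6 arrays, counts were 7 genes lower and list adjusted p was 0.0485 for interferon and mhc and 0.107 for sex genes. With probes well above background on at least 1 array, counts were 3 probes past the threshold, 3 genes higher and 0 genes lower and the chromosome 5 odds ratio was 3.29. With a variance trend, counts were 8 lists past the threshold by camera and list adjusted p was 0.0384 for deep layer neurons, 0.0384 for blood cells and 0.0402 for interferon and mhc. With a robust variance trend, counts were 22 genes lower and 8 lists past the threshold by camera and list adjusted p was 0.0384 for deep layer neurons, 0.0384 for blood cells and 0.0402 for interferon and mhc. With array quality weights, list adjusted p was 0.0460 for blood cells and 0.0219 for interferon and mhc. Under it, differences turned to -0.14 for Kcne2. With the mean over all probes of a gene, counts were 19 probes past the threshold. Under it, differences turned to -0.54 for Arsk, -0.32 for Map2, 0.024 for Syt1 and 0.078 for Epha5. With slide as a block, counts were 15 probes past the threshold, 4 genes higher, 6 genes lower and 8 lists past the threshold by camera and list adjusted p was 8.02e-04 for activity genes, 0.00419 for choroid plexus and 0.0211 for thalamus. Under it, differences turned to -0.10 for Slc4a1.

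For the chromosome 5 window, the odds ratio was 0 at 10 Mb and 9.32 at 40 Mb, 3.87 for the 200 genes of lowest p, 3.65 for these without the microglia list and 5.64 for genes with any called probe, and where under 5 called genes had a place on a chromosome the 200 stood in. At an unadjusted p under 0.01 with a fold over 1.5, 197 genes passed. Camera with an estimated correlation and fry called 0 lists each, with adjusted p by these tests of 0.354 and 0.0957 for microglia and for the clock list, 0.390 and 0.153 for astrocytes, 0.755 and 0.373 for striatum, and 0.354 and 0.0739 for sex-linked genes.

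Leaving out 1 array at a time gave 2 to 60 probes past the threshold, 2 to 23 genes higher, 0 to 21 genes lower and 5 to 9 lists past the threshold by camera, and a chromosome 5 odds ratio of 0 to 3.96. The probe count was 7 without control 15, 2 without control 16, 60 without knock-out 53 and 12 without knock-out 54. List adjusted p ranged from 0.0254 to 0.958 for activity genes, 0.0254 to 0.903 for oligodendrocytes, 0.00111 to 0.471 for blood cells, 5.55e-04 to 0.923 for choroid plexus, 6.58e-04 to 0.738 for olfactory bulb and 0.00201 to 0.208 for interferon and mhc. Differences ranged from -0.025 to 0.20 for the second Cux2 probe, -0.22 to 0.91 for Slc4a1, -0.034 to 0.30 for Igfbp2, -0.18 to 1.002 for Kcne2, -0.34 to 0.0075 for Synpo2, -0.56 to 1.54 for Tbx21 and -0.011 to 0.067 for Ddx3y.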

Other observations

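The planned test near Cux2 was of called genes. That of the 200 genes of lowest p was fixed beforehand as an alternative, and as a stand-in where under 5 genes were called. The bounds that tie it to DNA carried along with the locus were chosen only after the results were seen. So were the tests by separate distances, of blocks elsewhere, of the probed sequence, and those of control 16, of the slides and of RNA share on the microglia list. Some lists of neighbouring tissue or immune response stood apart on single arrays. Olfactory bulb markers averaged 1.73 on knock-out array 54 and between -0.54 and -0.16 on the other 5, as log2 deviation from each gene's mean. Interferon-response and MHC genes averaged 0.97 on control array 16 and between -0.37 and 0.10 on the other 5. Choroid plexus markers ranged from -0.88 on control array 15 to 0.86 on control array 62, and red blood cell transcripts from -0.98 on control array 62 to 0.86 on knock-out array 54.

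The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The labelled division called 33 probes, and the highest other division called 2, so 1 of 10 gave as many. For lists past camera's threshold the labelled division gave 5 and the highest other 9, and 7 of 10 gave as many, among them the division that follows the slides with 6; with slide as a block the labelled groups gave 8 lists, all at the preset correlation.

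Low-p genes near Cux2 were more frequent than elsewhere, by Fisher's tests that count neighbouring genes as independent. The planned test of called genes within 20 Mb did not pass, with an odds ratio of 1.98 (95% interval 0.0472 to 12.7, two-sided Fisher's exact p = 0.411). Against a difference between slides, the odds ratio of the 200 genes of lowest p within 20 Mb stayed at 3.00 (95% interval 1.66 to 5.06) with slide as a block. For these 200 genes 1 of 10 divisions of the arrays gave an odds ratio as large as 3.87, the highest other being 0.872, with divisions too few for a share under 0.05. DNA carried along from the stem cells of the targeted allele is a candidate explanation, by the odds ratio of 3.87, as a hypothesis weighed on values already seen, although the share of low-p genes was not highest nearest Cux2, at 3.37% up to 10 Mb against 6.50% from 10 to 20 Mb and 8.39% from 20 to 40 Mb (two-sided Fisher's exact p = 0.0629, nearest against both others). The origin of the allele and whether the controls carry 1 copy of it bear on this hypothesis and are not settled by the sources used here. Whether blocks elsewhere exist stays open. Of the 200 genes of lowest p off chromosome 5, a set other than the 200 above, 134 had another within 5 Mb against a mean of 127 for shuffled genes (permutation p = 0.199). The other divisions of the arrays gave 129 to 139. A change in probed sequence, not RNA level, may account for part, but the values cannot decide it. Another probe moved the same way in 4 of 14 genes over all chromosomes. These genes were chosen by a called probe, which alone makes a like move of another probe less likely. Probe sequences were not mapped, so probes of different transcript forms were not told apart. Of the 14 genes Aldh2, Hsd17b11 and Pkd2 lie within 20 Mb of Cux2, and for none of them did the other probe move the same way. The effect of lost Cux2 itself on the low-p genes near it stays untested.

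Microglial markers were lower on all 3 knock-out arrays. Control 16 as the whole source is argued against by a mean shift of -0.35 without it, where the standard error of the shift over all 6 arrays was 0.09. A slide difference is argued against by shifts of the same sign within both slides, -0.41 on slide 1 and -0.44 on slide 2. Each slide holds only 1 array of a group, so 0.09 does not measure the error of a within-slide shift. The labelled division gave a mean shift of 0.44 in size and the highest other 0.25, so 1 of 10 gave as large a shift, with divisions too few for a share under 0.05. A smaller share of microglial RNA could lower all 16 markers alike, and 2 of 16 had an interval that excludes the list's median of -0.39, Ly86 at -1.02 and Cx3cr1, a microglial chemokine receptor, at -0.01 (95% interval -0.25 to 0.22), which leaves it open. An effect of Cux2 loss and a difference in dissection stay untested.

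The Cux2 signal did not differ detectably between the groups. At an unadjusted p under 0.01 in limma, the labelled division gave 22 genes within 20 Mb of Cux2 and the highest other division 4. This argues against an exchange of 1 control with 1 knock-out array only if genes near Cux2 differ with the Cux2 genotype, which stays a hypothesis. The labelled division also called the most probes over all genes, 33 against 2 in the highest other, so its lead is not particular to the locus. An exchange of the whole groups would give the same counts and is not addressed by them. The position of the probes relative to the allele stays open.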
